A study of Corynebacterium glutamicum R with 3 samples.

How the data were processed

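Total RNA from the wild type of Corynebacterium glutamicum R, a Gram-positive soil bacterium used for amino acid production, was compared with RNA from a strain that lacks rnc, the gene of an RNase III homolog. RNase III is an endoribonuclease that cuts double-stranded RNA and takes part in the maturation of ribosomal RNA and in the decay of some messenger RNAs. Per the labels' protocols, cultures were grown aerobically at 33 °C in rich medium with 1% glucose, RNA was stabilised in the exponential phase at an optical density of 4, and cDNA of each strain was labelled with Cy3 or Cy5. Each of the 3 arrays held mutant and wild-type cDNA together. The mutant was in Cy5 on arrays 1 and 2 and in Cy3 on array 3, which the labels call a dye swap. The series text describes 3 separately performed experiments; the labels do not say how the cultures were paired.

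Per the file headers, the authors quantified the arrays with Agilent Feature Extraction under a 2-colour protocol; the headers give version 10.5.1.1 and the submitters' processing notes give version 10.5.5.1. The deposited intensity values used here were the median pixel intensity of each spot and of its local background, in both channels, with no normalization. Mean spot intensities were not used here, so the medians took the place of the mean signal that the planned correction named. The deposited processed intensity values and the deposited log10 ratio of red over green had, per the file headers, been background-subtracted and dye-normalized by the authors' software. Statistics of a spatial correction stand in the headers of arrays 2 and 3 but not in that of array 1; this step touches the processed values and not the raw medians. The authors' table of log2 ratios, deposited for the whole series, carried no statement of scale or direction. Set against the scanner ratios of the same arrays, its columns followed log2 of red over green on array 1 (r = 0.99, slope 1.00) and array 2 (r = 1.00, slope 1.00) and its negative on array 3 (r = -0.99, slope -0.99). It was therefore read as log2 of mutant over wild type, with column medians of 0.0088, 0.013 and 0.0027; how it was centred stays unknown. The deposited flags (other values, 0 or 1 per spot) marked spots well above background and outliers.

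The arrays carried 3278 numbered probes, each spotted at 2 places, 3 numbered control probes and 302 empty spots. The files give probe numbers and no gene: 0 of the 3278 probes had a systematic name, and 0 matched the gene table that was given, which describes another strain. No probe is therefore named as a gene. The planned check of the rnc transcript, the 26 gene lists fixed in advance, of which 0 could be tested, and the comparison of positions within a gene (there is 1 probe per number, without coordinates) were not run. The rule for probes named in the text was limited accordingly to the 2 with the largest rise and the 2 with the largest fall among those past the threshold with one direction on all 3 arrays.

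Background was corrected with normexp and an offset of 50 in limma 3.58.1 under R 4.3.3. Ratios were normalized by loess within each array, with weight 0 for control spots, empty spots and outlier spots (41 to 46 per array). The remaining spots of a probe were averaged. A probe was tested when both of its spots were well above background on at least 2 of 3 arrays in one genotype; 3188 probes were tested and 90 were not. The log2 ratio of array 3 entered with the opposite sign, and limma's moderated test (lmFit and eBayes, 2 residual and 3.90 prior degrees of freedom) compared the mean log2 ratio of mutant over wild type with 0, two-sided. P-values were adjusted by Benjamini-Hochberg over the probes tested, and a probe was called at an adjusted p under 0.05. The fit had no dye term, so part of any dye bias of a probe stays in its mean, because 2 arrays carry one dye orientation and 1 the other. Loess and centring set the bulk of probes to a ratio of 1, so a change shared by most transcripts cannot be seen. The offset pulls the ratios of dim probes towards 0.

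The fit was tested on simulated data: 3188 probes on 3 arrays with the noise estimated here, 200 of them changed, in 20 runs. The noise came from the fit without a dye term, so it already held part of any dye bias of the real arrays. The fit found 90.7% of the probes changed by 1 on the log2 scale and 23.7% of those changed by 0.5, with 4.23% false calls. With an added dye bias of SD 0.15 per probe it found 86.2% and 8.9%, with 3.17% false calls; a dye term in the fit then gave 84.7% and 8.1%, with 4.72% false calls. The number of arrays limits the precision. No saturated spot was marked. All 3 arrays were scanned on one day and the slides are not identified, so neither could be fitted as a batch.

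The gene lists, the test, the filter and the alternatives were fixed before the data were examined. The alternatives were no background correction, normexp with offset 0, the processed signals, median centring in place of loess, scaling between arrays, other filters on dim probes, the authors' log2 ratios, a dye term, the channels as separate samples with and without the array as a block, moderation with an intensity trend, the median over the spots of a probe, and each array left out in turn. Tests on neighbouring probe numbers used Spearman's rank correlation across probes, which are not independent replicates, and 1000 shuffles of the numbers.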

Results

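The transcriptome of an rnc deletion mutant of C. glutamicum R was measured against that of the wild type in exponentially growing cultures, on 3 two-colour arrays of 3278 probes. The series asks which transcripts change when the RNase III homolog is missing. Median spot signals of the mutant channel were 3424.5, 2872.5 and 1702 on arrays 1, 2 and 3, against median local backgrounds of 143, 121 and 162. Those of the wild-type channel were 1818.5, 2290.25 and 3109.75, against 140, 150 and 119. The channel in Cy5 was the brighter one on each array. Between 94.4% and 98.4% of the probe spots were well above background per channel, and 0 of the 302 empty spots were on any array.

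The 2 spots of a probe gave closely similar ratios. Their correlation was 0.918, 0.979 and 0.964 on arrays 1 to 3, and the SD between spots was 0.10, 0.066 and 0.090 on the log2 scale. The spread between arrays was larger, with a median SD of 0.20 per probe (n = 3). Across the 3188 tested probes, which are not independent replicates, the log2 ratios of arrays 1 and 2 correlated with Pearson's r = 0.76 (Spearman's rho = 0.74). Array 3, the dye swap, correlated less closely with array 1 (r = 0.46, rho = 0.38) and array 2 (r = 0.40, rho = 0.35). All 3 correlations were positive once array 3 was turned, which is the relative orientation that the dye labels give.

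**Figure D1:**
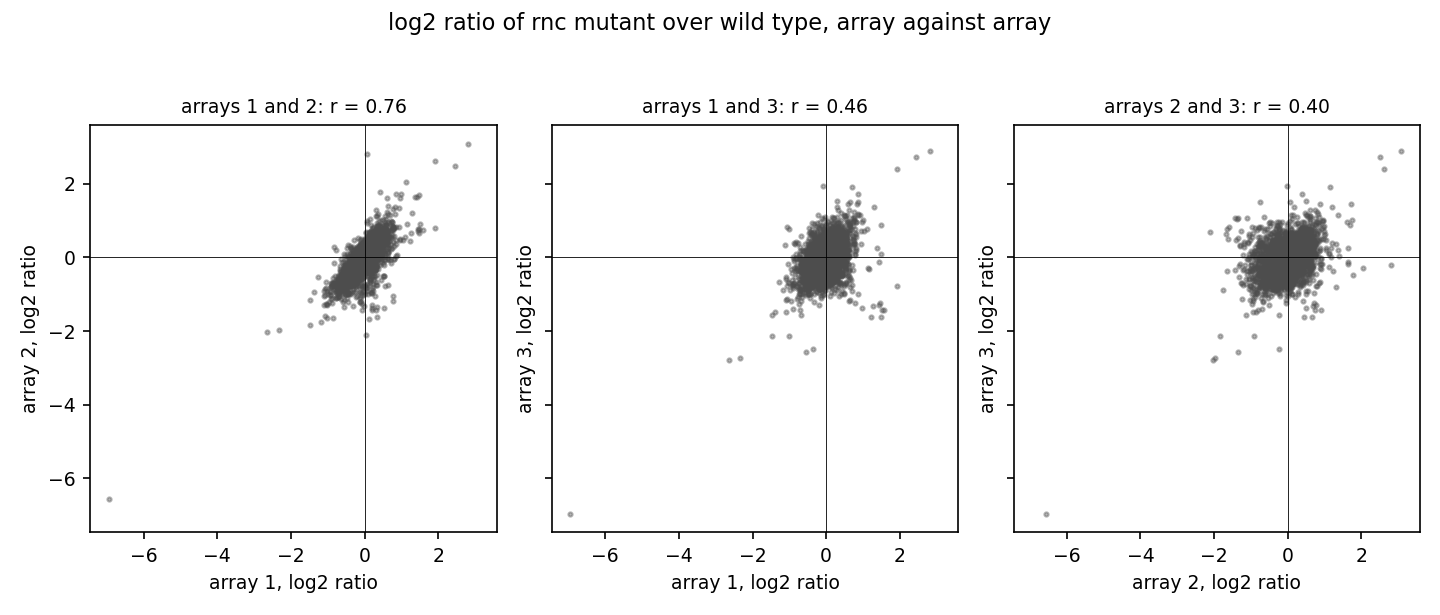
Each point is 1 of the 3188 tested probes, with its log2 ratio of rnc mutant over wild type on one array (x axis) against another (y axis), array 3 being turned for its swapped dyes. The cloud is narrower for arrays 1 and 2 (r = 0.76) than for either of them with array 3 (r = 0.46 and 0.40), and 1 probe lies far below 0 on every array.

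Deletion of rnc was accompanied by changes in 186 of the 3188 tested probes (5.83%), of which 74 were higher and 112 lower in the mutant (limma, Benjamini-Hochberg adjusted p under 0.05). Most of these changes were small: 164 of the 186 were under 2-fold in the mean. Among the probes that rose, 10 rose at least 2-fold, and the median log2 ratio was 0.71. Among the probes that fell, 12 fell at least 2-fold, with a median log2 ratio of -0.73. Of all tested probes, 89.2% had a mean log2 ratio between -0.5 and 0.5. At an unadjusted p under 0.05 there were 982 probes. The count rested on single arrays and on the treatment of the dye. It was 8 without array 1, 165 without array 2 and 829 without array 3. Of the 186 probes, 8, 123 and 186 were called again in these fits. Each fit estimated the spread anew from 2 arrays, so the counts also reflect that estimate. Arrays 1 and 2 both carry the mutant in Cy5, so among those 829 a dye bias cannot be told from a change. With a dye effect fitted per probe the count was 1020 (486 higher, 534 lower). From the authors' log2 ratios the same test called 11 probes, 4 higher and 7 lower, all of them among the 186.

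**Figure D2:**
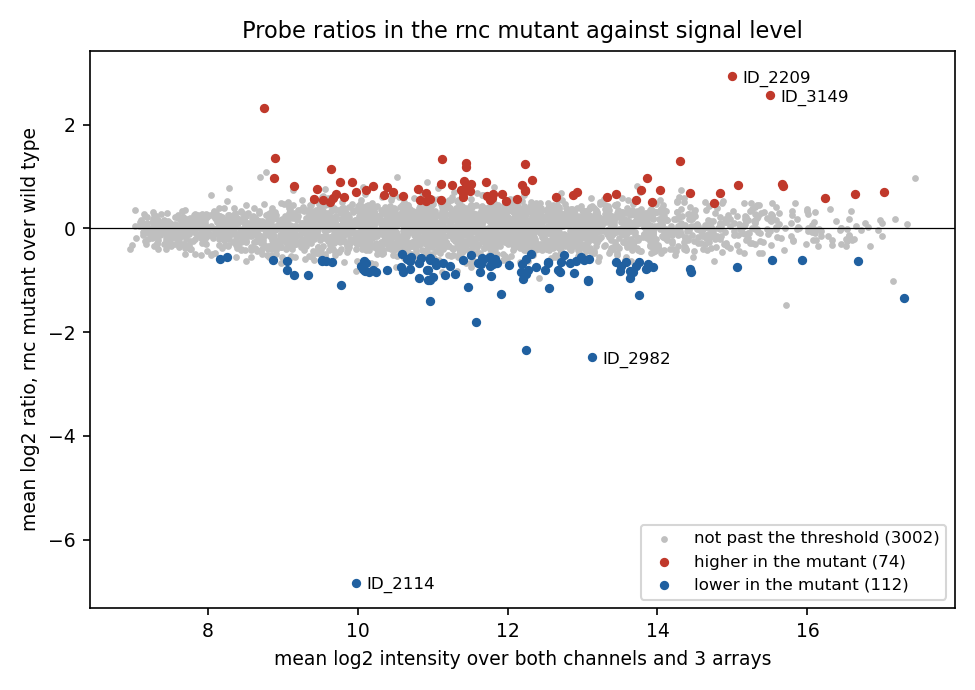
The mean log2 ratio of rnc mutant over wild type (y axis, 3 arrays) of the 3188 tested probes is plotted against their mean log2 intensity (x axis); red points are the 74 probes called higher and blue points the 112 called lower in the mutant. Called probes occur at all signal levels, most lie between -1 and 1, and ID_2114 stands apart at -6.82, with its mutant signal near background.

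Calls were spread over the range of signal. Of the 638 dimmest probes 1.57% were called, 4 higher and 6 lower. Of the 638 probes around the median signal 8.93% were called, 23 higher and 34 lower. Of the 638 brightest 6.58% were called, 19 higher and 23 lower. The median SD between arrays was 0.22 in the dimmest and 0.18 in the brightest of these sets. Of the tested probes, 1693 (53.1%) kept one direction on all 3 arrays, from 37.9% of the dimmest to 61.1% of those around the median signal. Arrays 1 and 2, which share a dye orientation, agreed in direction for 79.1% of the tested probes; with a random sign on array 3, 39.6% would keep one direction on all 3.

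A change of at least 2-fold in one direction on every array was seen for 11 probes, 4 higher and 7 lower in the mutant, and all 11 passed the test. The split moved with the setting, to 7 higher and 7 lower with normexp at offset 0, with the processed signals and from the authors' log2 ratios, to 8 and 8 without array 1, and to 8 and 14 without array 3. ID_2114 showed the largest change. Its signal was well above background in the wild-type channel on all 3 arrays, at 8936.5, 8988.25 and 16821. It was not well above background in the mutant channel on any, with 189, 170 and 168.75 beside local backgrounds of 136, 120 and 162. These signals of ID_2114 are median spot signals averaged over 2 spots, before correction and normalization. Its log2 ratio was -6.82 ± 0.22 (SD, n = 3), with an adjusted p of 1.06e-05 by limma. Measured against the lowest signals well above background, it was at least 80.1-fold lower in the mutant after normexp correction. That bound holds for this correction only and is taken from channel values after loess and Aquantile normalization, which remain open to dye bias because the swap is unbalanced. Because the mutant value lay near background, the fitted log2 ratio moved with the correction, to -6.00 with no background correction and to -8.56 from the authors' log2 ratios. Whether ID_2114 is the probe of rnc is not given by the files.

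Among the probes measured in both genotypes, ID_2982 fell by 2.48 on the log2 scale (SD 0.40, n = 3; 5.59-fold; limma adjusted p = 0.0043), with ratios of -2.65, -2.03 and -2.77 on the single arrays. ID_2209 rose by 2.93 (SD 0.14, n = 3; 7.64-fold; limma adjusted p = 0.00036). Its ratios were 2.82, 3.08 and 2.90. Its median spot signals, averaged over 2 spots, were 101264, 130492 and 65653.5 in the mutant channel. In the wild-type channel they were 7568.25, 11364.8 and 16983.5. These signals are neither background-corrected nor normalized, so they do not give the ratios directly. ID_3149 rose by 2.56 (SD 0.16, n = 3; 5.91-fold; limma adjusted p = 0.00062), with ratios of 2.45, 2.50 and 2.74. The 2 other probes that rose at least 2-fold on every array had mean log2 ratios of 2.32 and 1.29. The 5 others that fell had mean log2 ratios from -2.34 to -1.09. These 4 named probes passed the test in every alternative in which they were tested, with each array left out in turn included.

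**Figure D3:**
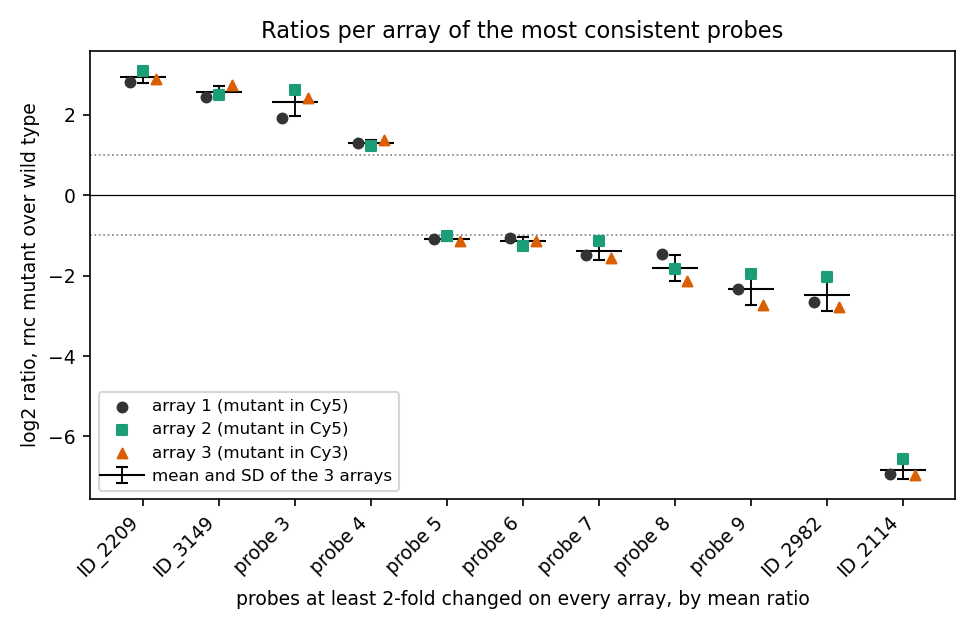
The log2 ratio of rnc mutant over wild type (y axis) on each of the 3 arrays is shown for the 11 probes that changed at least 2-fold on every array (x axis, ordered by mean); bars are means and SDs of the 3 arrays, and dotted lines mark a 2-fold change. The probes were chosen for one direction on all 3 arrays, so the shared direction of the dye-swapped array is given by the choice. Mean ratios ran from 2.93 for ID_2209 to -6.82 for ID_2114. The mutant signal of ID_2114 lay near background, and its ratio ranged from -8.56 to -6.00 with the processing.

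Signal in 1 genotype alone was rare. Besides ID_2114, 1 other probe was well above background in the wild type on all 3 arrays and not well above it in the mutant on any; both its levels lay near background and its ratio did not pass the test (limma adjusted p = 0.28). No probe (0 of 3278) was well above background on every array in the mutant alone.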

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

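The tests in this part were chosen after the arrays had been examined. One of the 3 control probes, which enter no comparison, gave signal: 11 of its 12 spot channels (6 spots, both dyes) were well above background, where 0 of the 302 empty spots were. Its uncorrected median spot signals, averaged over 2 spots, were 391.75, 276.75 and 252 in the mutant channel of arrays 1 to 3. In the wild-type channel they were 186.75, 258.75 and 293.5. The other 2 control probes had 0 of 12 spot channels well above background. The files do not say what the control probes are. Groups of 3 arrays are too small for a check of single outlying values, and the series holds no second contrast to compare.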

How the results depend on the processing

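Of 64 recomputed counts, 39 stayed within 1.5 times the value reported and 25 did not; the 63 recomputed ratios of the 4 named probes all kept their direction and their side of the threshold. Log2 ratios ranged from 2.86 to 2.99 for ID_2209, 2.47 to 2.62 for ID_3149, -2.71 to -2.34 for ID_2982 and -8.56 to -6.00 for ID_2114, with adjusted p of at most 0.020. No probe among the 186 changed sign under any alternative (0 of 186 in each, except 0 of 185 where both channels had to be well above background on all arrays and ID_2114 was not tested). The 186 and the 4 named probes were chosen by their ratios on these same spots, so a kept sign is little support. The count of 186 (74 higher, 112 lower) became 118 (41 higher) with normexp at offset 0, 69 (23 higher, 46 lower) with the processed signals, 11 (4 higher, 7 lower) with the authors' log2 ratios and 1020 (486 higher, 534 lower) with a dye term; an intensity trend in the moderation gave 112 higher, in a total of 262. The cause was not tested. All 186 were among the 1020, whose spread by construction comes from the difference of arrays 1 and 2 alone. Each array holds both genotypes, so the pairing is physical: with channels as separate samples the count was 16 (7 higher, 9 lower) with no replicate block and 376 (176 higher, 200 lower) with the array as replicate block. Leaving out 1 array gave 8 to 829 calls, 4 to 396 higher and 4 to 433 lower. The count of probes at least 2-fold changed on every array, 11, was 14 to 22 with 1 array left out, where 2 arrays instead of 3 must pass, and 10 to 14 otherwise. The median over 2 spots equals their mean, so that setting moved nothing. Nor could the 2-fold count move with a dye term, an intensity trend or channels as separate samples, which leave each array's ratios as they were. These counts are among the 39 and are no support. A slide or scan block was not run, nor were gene lists and positions within genes, since the files name no genes. Few dim probes were called: 1.57% of the 638 dimmest passed. Whether fewer of them changed or fewer changes could be detected was not tested.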

Other observations

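The tests of the position of the spots, of the cultures and of the deleted gene were set before their values were seen; those of a shared signal level, single-probe dye bias, printing order, failed spots, runs of numbers and sign assignments were chosen after the result was seen.

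Probes with consecutive numbers changed together. Of the 74 probes called higher in the mutant, 16 had a directly adjacent number that was also called higher; shuffled numbers gave 3.19 in the mean and at most 13 (permutation p = 0.001, the smallest that 1000 shuffles can give; Benjamini-Hochberg adjusted p = 0.002 over both directions). Of the 112 called lower, 17 had such a neighbour, against 7.47 in the mean and at most 24 (permutation p = 0.015, adjusted p = 0.015). The shuffles do not allow for signal level. Mean intensity correlated at 0.371 between consecutive numbers, and the share called varied with signal, from 1.57% to 8.93%. There were 2 runs of 3 consecutive numbers among the risen probes, with log2 ratios from 1.18 to 1.34 in one and from 0.84 to 0.92 in the other, and 1 run of 3 among the fallen ones, from -1.81 to -0.85; shuffled numbers also reached runs of 3 or more. Across all tested probes the mean log2 ratio of consecutive numbers had a rank correlation of 0.21 (3105 pairs), where shuffled numbers gave at most 0.061. The difference between arrays 1 and 2, which have the same genotypes and dye orientation, was shared by consecutive numbers at 0.26. Sharing among neighbours is thus not limited to the change in the mutant.

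A shared signal level was examined in the ratios after loess. In the loess-normalized ratios consecutive numbers correlated at 0.206. Exchanging these ratios among 20 probes of like intensity gave at most 0.051 in 1000 exchanges (SD 0.018). After loess the ratios hardly followed intensity (Spearman's rho = 0.031). The exchange keeps whatever dependence on intensity these ratios had. Its values therefore argue against such a dependence as the source of the 0.206. They cover the ratios after loess, and not the counts of called neighbours. The test planned first, which removed a dependence on intensity after loess, moved nothing (0.206 to 0.205), since little dependence was left to remove. The position of the spots was not excluded. Probes placed 2 rows apart whose numbers differ by more than 10 correlated at 0.033 (SD of shuffled values 0.026, 1476 pairs). This is below the 0.10 set beforehand as the least that position would give. Consecutive numbers correlated at 0.171 at that spacing and at 0.245 when placed at least 10 spots apart. However, each probe was placed at the lowest row and the lowest column of its 2 spots, each found separately. That place may be no real spot of the probe, and the ratio averages 2 spots, so these values do not decide. A source plate or print pass that spans well over 10 numbers would be shared at a distance of 10 numbers, where the correlation was 0.013. How many numbers a plate or pass holds is not known. The value therefore cannot decide on shorter units of printing. A numbering that follows gene order, with neighbours transcribed together, is a candidate explanation; it stays untested because no table used here pairs the numbers with genes.

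The dye-swapped array followed the other 2 less closely than these followed each other. A dye term raised the calls from 186 to 1020, and by construction its spread comes from the difference of arrays 1 and 2 alone. In simulated arrays with a dye bias of SD 0.15 per probe calls did not rise (151.55 in the mean, against 151.4 without the term). Their noise came from the fit without a dye term and so already held the departure of array 3. The simulation therefore cannot tell why calls rose here. The part of the ratio in which array 3 differed from the mean of arrays 1 and 2 was shared by consecutive numbers (rank correlation 0.198 after intensity). It was hardly shared by probes placed 2 rows apart with distant numbers (0.034, SD of shuffled values 0.026). Probes were placed as described above, so this does not decide on the position on the array. Sharing among neighbours would count against a dye bias of single probes, but the test does not decide: 6 consecutive numbers were brighter in red than in green on every array, by 1.41, 0.71 and 1.39 on the log2 scale (SDs between probes 0.14, 0.15 and 0.14), where shuffled numbers gave runs of at most 2, so a dye bias may itself be shared by neighbours. None of these 6 was called (0 by limma), which follows from how they were chosen. Once array 3 is turned, its ratios oppose those of arrays 1 and 2. The lack of calls therefore does not tell whether dye bias entered the calls. A difference between the cultures and a dye bias cannot be told apart with 1 swapped array; the difference between arrays 1 and 2, which have one dye orientation, was shared by consecutive numbers as well (0.26).

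ID_2114 lost its signal in the mutant alone. Failed spots are argued against, since a failed spot would be dim in both channels: all 6 of its spots had a wild-type channel well above background beside a dim mutant channel, under both dye orientations. Spots that hold another sequence than intended were not tested. It was the only 1 of the 3188 tested probes with this pattern and a log2 ratio under -2. A candidate explanation is that it is the probe of the deleted gene, which the files used here leave open.

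Other assignments of signs to the 3 arrays gave 0 calls at most (by limma; 8 to 131 probes at an unadjusted p under 0.05), against 186 with the signs the dye labels give (1 of 4 assignments reached as many). With 4 assignments no share under 0.05 can be reached.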
